A study of Mus musculus with 14 samples.

How the data were processed

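Gene expression was compared between mouse embryos made by in vitro fertilisation (IVF) and by somatic cell nuclear transfer (SCNT, in which the nucleus of a body cell replaces that of an oocyte), and the cumulus cells that supplied the nuclei. There were 14 RNA-seq libraries in 7 groups of 2: donor cumulus cells, IVF 1-cell, SCNT 1-cell, IVF 2-cell and SCNT 2-cell embryos, and SCNT 2-cell embryos overexpressing Kdm4d, a demethylase of histone H3 lysine 9, or a mutant Kdm4d. The mutation and the way of overexpression are not given in the sources used here. Per the labels' protocols, lysed embryos went into SMARTer Ultra Low Input cDNA synthesis, Covaris fragmentation and NEBNext Ultra library preparation, with single-end reads of 50 bases on a HiSeq 2500. Per the strain labels, donor cells were (C57BL/6J x CAST/EiJ) F1, recipient oocytes B6D2F1 and IVF embryos C57BL/6J oocyte x CAST/EiJ sperm. The labels' protocols name BDF1 females as the source of the cumulus cells instead, a conflict that the sources used here do not settle. Embryos were pooled, and nothing in the labels says that the replicates were separate experiments.

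Per the submitters' processing notes, reads were handled with Novoalign (version not given) and Cufflinks 2.0.2 on genome build mm9. The deposited table, made by the authors, holds FPKM, fragments counted relative to transcript length and to all mapped fragments, for 23697 rows and all 14 libraries. Filters, annotation and the treatment of reads that map to several places are not given in the sources used here. The start coordinates in the table count from 0: for 20482 matched symbols, 8694 single-interval lengths equalled end minus start and 527 equalled end minus start plus 1, so 1 was added to each start printed.

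From the table, 790 rows of short RNAs were left out by name, because FPKM of transcripts shorter than a fragment is unreliable. The 710 rows that shared a symbol were summed per library, which left 22498 symbols. The 13455 genes with at least 1 FPKM in at least 2 libraries were tested. Values were taken as log2(FPKM + 1) with no further scaling, which understates the changes of genes near 0. All 7 group means were fitted in a single model with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend, 7 residual degrees of freedom, median prior degrees of freedom 4.71). P-values were adjusted by Benjamini and Hochberg within each comparison at a threshold of 0.05. They measure only the spread between these libraries.

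The comparisons were donor cells with IVF 1-cell embryos, SCNT with IVF embryos at each stage, the stage change in each kind of embryo and its interaction, and each Kdm4d group with SCNT 2-cell embryos, with each other, or (wild-type Kdm4d) with IVF 2-cell embryos. Overlaps of called genes were tested with Fisher's exact test, two-sided. Where comparisons shared libraries, Spearman's rho across genes was set beside 20 simulations of unchanged groups. Overlaps of comparisons that share a group were counted again with 1 library of that group given to each comparison, in both ways. The comparison of the Kdm4d groups with each other shares no library with that of SCNT and IVF 2-cell embryos.

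Sets of genes were tested with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. The 24 lists were 2-cell-stage transcripts, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, spliceosome, oxidative phosphorylation, maternal oocyte transcripts, markers of cumulus and granulosa, immune, endothelial, oviduct epithelial, red blood and sperm cells, histone H3 lysine 9 methyltransferases and readers, histone H3 lysine 9 demethylases, DNA methylation, histone deacetylases, imprinted genes, pluripotency and lineage factors, p53 and stress response, immediate early genes, the Magea and Xlr clusters of the X chromosome, histone genes, and DNA replication and cell cycle. Lists with under 3 tested members had no camera test.

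Groups, comparisons, lists, their tests and the alternatives named next, except the group weights, were chosen before the data were examined. The tests of collection time, of genes with no shared stretch, of scaling and by chromosome, the overlaps counted on split libraries or with group weights, and the sizes of shared stage changes, were chosen after results were seen. The genes named were, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall among those with a mean of at least 5 FPKM in a group and no overlap between the libraries compared. Of each list described, up to 2 members that rose and 2 that fell were named, or where none was called the 2 most abundant, and Kdm4d in every group. The text gives a selection of these. Genes with over 30% of their stretches shared, and members of families with over 15%, have their values called uncertain. The quantile-normalized counts of a called list are given where its larger count moved by over 1.5 times.

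The alternatives were a pseudocount of 0.1, no filter, quantile normalization, a fit to only the groups compared, a block for replicate number, and leaving out each library in turn. Group weights, in which limma's arrayWeights gives each group its own variance, were added after the spread between replicates was seen to differ between groups. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for sequence sharing and plots. Stretches of 50 bases, 1 in 4 sampled, were compared between the transcripts of GRCm38 in GENCODE M21, which 12143 of the tested genes (90.2%) matched by symbol, and 26.7% of tested genes shared over 5% of their stretches with another gene.

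Total reads per library are not given in the sources used here, so no absolute depth, counting interval or limit for a value of 0 was computed. Depth relative to IVF 1-cell replicate 1 was estimated from the steps between the lowest values. The fit was tested on simulated data by planting changes in SCNT and IVF 2-cell libraries: of 100 genes each, 61% of planted 2-fold and 98% of planted 4-fold changes were called, with 6 false calls (3.64% of calls). Camera called 1% of 200 random lists of 40 genes. Both simulations drew values independently between genes, with 1 variance per gene for all groups. They thus do not cover lists whose members vary together, or differences in spread between groups. Samples had no sequencing dates or batches in the labels, so no batch could be examined. Groups of 2 were too small for outlier tests of single libraries or for counts over other splits of the samples.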

Results

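The libraries covered pools of 32 and 31 IVF 1-cell, 36 and 36 SCNT 1-cell, 25 and 25 IVF 2-cell and 40 and 40 SCNT 2-cell embryos, 25 embryos in each Kdm4d and mutant Kdm4d library, and about 1000 donor cells each. Sums of FPKM ran from 183063 to 345418, and between 8451 and 10788 genes reached 1 FPKM. The sums were lowest in SCNT 2-cell libraries, at 187454 and 183063. They were 242742 and 235703 in IVF 2-cell, 291640 and 310341 in Kdm4d and 280747 and 233811 in mutant Kdm4d libraries. Comparisons of these groups thus rest on unequal sums, and values were not scaled to equal ones. The donor and Kdm4d libraries were the shallowest. Relative to the deepest library at 1, the Kdm4d libraries had depths of 0.508 and 0.415, the mutant libraries 0.462 and 0.497, the donor libraries 0.59 and 0.586, and all others at least 0.779. Spearman's rho across genes between the replicates of a group ran from 0.932 (mutant Kdm4d) to 0.988 (IVF 1-cell). Among 6256 genes with a mean of at least 5 FPKM, the robust SD between replicates on the log2 scale was 0.093 in IVF 1-cell, 0.1 in SCNT 1-cell, 0.142 in IVF 2-cell, 0.184 in SCNT 2-cell, 0.368 in Kdm4d and 0.373 in mutant Kdm4d embryos. Unless another fit is named, each limma SE and p-value below rests on 1 variance per gene for all groups. Those of single genes in comparisons with a Kdm4d or mutant Kdm4d group may thus understate the spread of these groups. The first 3 principal components held 50%, 34.4% and 7.75% of the variance. Levels below are mean FPKM ± SD of 2 libraries, positions are on mm9 with starts counted from 1, and every gene named as changed had no overlap between the libraries of the groups compared. Gm13078 of the PRAME family cluster shares 19.7% of its 50-base stretches with other genes, Obox3 of the oocyte homeobox family 19.6%, the glutathione transferase gene Gstm1 21% and the ribosomal protein gene Rpl41 15.3%, so their values are uncertain throughout.

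Kdm4d (chromosome 9, 14267025 to 14304926) lay below 1 FPKM in every library without overexpression. Its levels were 0.127 ± 0.0353 in donor cells, 0.0797 ± 0.0672 in IVF 1-cell, 0.145 ± 0.0907 in SCNT 1-cell, 0.587 ± 0.243 in IVF 2-cell and 0.435 ± 0.153 in SCNT 2-cell embryos. In Kdm4d embryos it reached 5570 ± 4680 FPKM, and in mutant Kdm4d embryos 503 ± 311, a log2 difference of 3.30 (SE 0.52, adjusted p = 0.00048, but 0.11 in a fit to these 4 libraries only and 0.0033 with group weights). What was introduced, and how much of its sequence the gene model covers, is not given in the sources used here, so these are values as measured and not construct abundance.

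**Figure D1:**
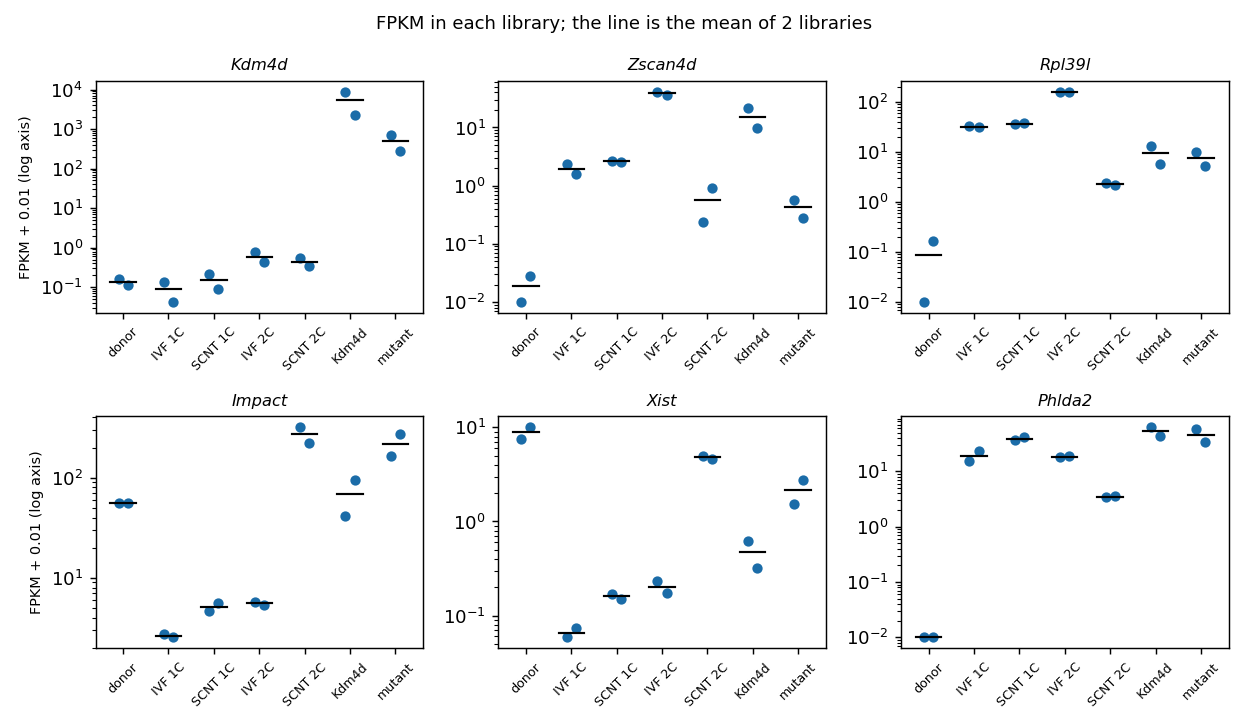
FPKM of 6 genes in each library (log axis, 0.01 added; points are libraries, lines are means of 2). Kdm4d stands at 5570 FPKM in Kdm4d and 503 in mutant Kdm4d embryos, and Zscan4d at 39 in IVF 2-cell, 0.563 in SCNT 2-cell and 15.4 in Kdm4d embryos; Xist was chosen after its values were seen.

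Donor cumulus cells differed from IVF 1-cell embryos in the transcripts of steroid-making ovarian cells on one side and of the oocyte on the other. Spp1, which encodes the secreted protein osteopontin (chromosome 5, 104864130 to 104870072), stood at 14400 ± 3220 FPKM in donor cells against 0.336 ± 0.376 in IVF 1-cell embryos. Akr1c18, which encodes a progesterone-metabolising enzyme, stood at 3440 ± 314 against 0.0569 ± 0.0805. Cyp11a1, the gene of the enzyme that begins steroid synthesis, stood at 1790 ± 639 and was listed at 0 in the embryos, and Gja1, the gene of the gap junction protein connexin 43, stood at 2040 ± 18 against 0.688 ± 0.0759. Btg4, needed for the clearance of maternal mRNA, had 0.55 ± 0.0571 FPKM in donor cells against 5310 ± 89.8 in embryos, and Bcl2l10 0.244 ± 0.0444 against 3850 ± 168. By limma, 5703 genes were higher and 4779 lower in donor cells. Of 58 cumulus and granulosa markers, 55 were higher and 3 lower, the same counts adjusted over the list alone (camera adjusted p = 3.93e-13, and adjusted p = 0.0131 with an estimated correlation). Among 65 maternal transcripts 1 was higher and 63 lower, the same adjusted over the list alone (adjusted p = 4.46e-23, and adjusted p = 0.115 with an estimated correlation). All 19 immediate early genes were higher, also adjusted over the list alone (adjusted p = 4.3e-06, and adjusted p = 0.115 with an estimated correlation). Marker lists of other cell types had few tested genes: 8 of 13 immune, 1 of 5 endothelial, 3 of 6 oviduct epithelial, and 0 of 6 sperm markers were higher in donor cells, and camera called none of them. Adjusted over the list alone the counts higher were 8, 1, 3 and 0. The 1 red blood cell marker tested was higher too, with no camera test.

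At the 1-cell stage, most of the genes called higher in SCNT than IVF embryos were also higher in donor cells. Akr1c18 rose to 31.3 ± 10.5 from 0.0569 ± 0.0805 FPKM (log2 4.90, SE 0.38, adjusted p = 1e-04), and Spp1 to 25 ± 4.04 from 0.336 ± 0.376 (adjusted p = 0.00069). Gt(ROSA)26Sor, a widely transcribed noncoding locus, rose to 8.8 ± 0.77 from 0.287 ± 0.205 (adjusted p = 9.6e-05), and Ankrd7 to 10.1 ± 0.806 from 0.572 ± 0.0434 (adjusted p = 0.0012), although Ankrd7 was nearly absent from donor cells at 0.111 FPKM. Ccdc117 fell to 19.3 ± 1.63 from 87.9 ± 1.64 (log2 −2.13, SE 0.17, adjusted p = 1e-04). Txnip, which encodes an inhibitor of thioredoxin, fell to 22.7 ± 0.508 from 95.1 ± 2.18 (adjusted p = 0.00013), and Rdx, the radixin gene, to 241 ± 0.578 from 704 ± 7.67 (adjusted p = 0.0016). By limma, 180 genes were higher and 131 lower. Of the 180, 147 (81.7%) were also higher in donor cells than in IVF 1-cell embryos (odds ratio 6.19, 95% interval 4.21 to 9.34, Fisher's exact p = 1.66e-27), against 14 of the 131 (10.7%). Both comparisons use the IVF 1-cell libraries, which by itself raises the overlap. With 1 IVF 1-cell library given to each comparison, 42 of 47 and 34 of 36 higher genes were also higher in donor cells (odds ratios 12.9 and 26), and 1 of 10 lower genes in either split. Cumulus and granulosa markers rose in 10 and fell in 0 of 58 cases, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.0025, but adjusted p = 0.528 with an estimated correlation), with Cyp11a1 at 2.66 ± 0.297 FPKM and listed at 0 in IVF embryos. Maternal transcripts fell in 6 of 65 cases and rose in 0, or 10 and 0 adjusted over the list alone (adjusted p = 5.17e-12, but adjusted p = 0.881 with an estimated correlation), and 1 fell after quantile normalization. The counts changed with the spread assumed, the scaling and the pseudocount. They were 78 and 66 after quantile normalization, and 601 genes were higher with a pseudocount of 0.1. They were 1609 and 1166 in a fit to these groups only, and 2548 and 1530 with group weights, which kept all 180 and 131. They were 36 to 47 higher and 7 to 11 lower without any single library of either group. Strain differed with the kind of embryo, since per the labels the IVF oocytes were C57BL/6J and the SCNT recipient oocytes B6D2F1.

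Between the 1-cell and 2-cell stages after IVF, transcripts absent before became abundant, and stored oocyte transcripts were lost. Gm11517 (chromosome 11, 96656646 to 96659470) rose from 0.233 ± 0.213 to 1250 ± 86.7 FPKM (log2 9.99, SE 0.45, adjusted p = 4.8e-09). Obox6, of the oocyte-specific homeobox family, rose from 0.296 ± 0.0749 to 705 ± 12.9 FPKM (log2 9.09, adjusted p = 3.8e-09). The homeobox gene Crxos1 rose from 0.171 ± 0.0825 to 482 ± 1.98 (adjusted p = 7.5e-10). Trim43a, whose family members share sequence so that its values are uncertain, rose from 0.0451 ± 0.0637 to 362 ± 18 (adjusted p = 9.9e-10). Crabp2, the gene of a retinoic acid binding protein, fell from 350 ± 29.8 to 5.05 ± 0.469 FPKM (log2 −5.86, SE 0.21, adjusted p = 1e-09). Rgs2, a regulator of G protein signalling, fell from 402 ± 18.2 to 6.36 ± 0.378 (adjusted p = 1.7e-10), and the DNA repair gene Neil3 from 194 ± 2.65 to 3.29 ± 0.704 (adjusted p = 5.4e-09). By limma, 4086 genes rose and 5000 fell.

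Several lists moved with this transition in IVF embryos. Among 38 transcripts of the 2-cell stage 35 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 8.82e-13, and adjusted p = 0.0406 with an estimated correlation). Several members are of families with shared sequence, such as Gm5662 with 77.8% and Gm8994 with 48% of stretches shared, while Hspa2 and Ddit4l shared 0%. Reads may thus count for several members, so the counts and p-values of this list are uncertain in every comparison. Cytosolic ribosomal proteins rose in 73 and fell in 2 of 82 cases, the same adjusted over the list alone, with Rpl41 going from 6.36 ± 0.439 to 647 ± 3.2 FPKM (adjusted p = 1.21e-17, but adjusted p = 0.155 with an estimated correlation). Ribosome biogenesis genes rose in 52 and fell in 7 of 69, or 52 and 8 adjusted over the list alone (adjusted p = 2.89e-09, but adjusted p = 0.633 with an estimated correlation), and Nop16 went from 0.0887 ± 0.0575 to 210 ± 16.7 FPKM. Maternal transcripts fell in 60 and rose in 3 of 65, the same adjusted over the list alone, with Oog4 going from 753 ± 21.6 to 21.6 ± 0.22 FPKM (adjusted p = 1.08e-12, but adjusted p = 0.588 with an estimated correlation). Oxidative phosphorylation (44 rose, 17 fell of 82), the p53 and stress list (18 and 7 of 32) and the Magea and Xlr clusters (0 and 6 of 7), with the same counts adjusted over each list alone, passed camera (adjusted p = 0.0142, 0.0218 and 0.0214) but not with an estimated correlation (adjusted p = 0.588, 0.588 and 0.633). Kdm4c, a demethylase of the same family as Kdm4d, rose from 0.125 ± 0.0268 to 34.8 ± 2.62 FPKM (adjusted p = 5e-09), while 4 of 11 histone H3 lysine 9 demethylases rose and 4 fell, the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.609).

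In SCNT embryos the same stages brought changes in many of the same genes. Trim43a, with the uncertainty named, rose from 0.304 ± 0.0493 to 157 ± 6.49 FPKM (log2 6.92, SE 0.30, adjusted p = 1.3e-08), Gm11517 from 0.205 ± 0.122 to 98 ± 0.0197 (log2 6.36, SE 0.45, adjusted p = 2.9e-07). Cd63, a gene of a vesicle membrane protein, rose from 0.221 ± 0.191 to 111 ± 34.9 (adjusted p = 5.9e-08). Slbp, whose product binds histone mRNA, fell from 1130 ± 18.1 to 25.5 ± 3.87 FPKM (log2 −5.42, SE 0.17, adjusted p = 2.8e-09), and Neil3 from 140 ± 10.3 to 3.13 ± 0.317 (adjusted p = 2.8e-08). By limma, 4773 genes rose and 4243 fell. Of the 4086 genes that rose in IVF embryos, 3093 (75.7%) also rose here, and of the 5000 that fell, 3656 (73.1%) also fell. The rise was smaller in SCNT embryos in 1962 of the 3093 (63.4%) and larger in 1131, and by the interaction test 798 and 234 of these were called. The fall was smaller in 2541 and larger in 1115 of the 3656, with 549 and 133 called. Transcripts of the 2-cell stage rose in 21 and fell in 4 of 38 cases, the same adjusted over the list alone (camera adjusted p = 0.0224, but adjusted p = 0.526 with an estimated correlation). Ribosomal protein genes rose in 64 and fell in 6 of 82, the same adjusted over the list alone (adjusted p = 2.55e-09, but adjusted p = 0.406 with an estimated correlation). Maternal transcripts fell in 58 and rose in 2 of 65, or 61 and 2 adjusted over the list alone (adjusted p = 4.51e-16, but adjusted p = 0.406 with an estimated correlation).

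**Figure D2:**
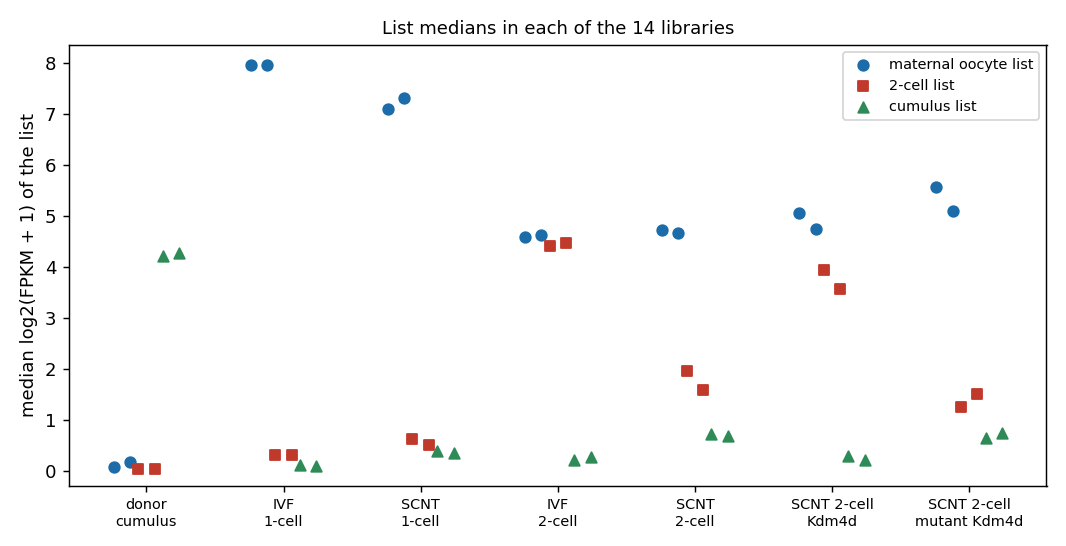
Median log2(FPKM + 1) of the maternal, 2-cell-stage and cumulus lists (vertical axis) in each of the 14 libraries (points, by group). The 2-cell-stage median is 4.42 and 4.47 in IVF 2-cell, 1.95 and 1.59 in SCNT 2-cell, 3.94 and 3.56 in Kdm4d and 1.25 and 1.5 in mutant Kdm4d embryos.

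The difference between the stage changes was tested itself. By limma, 2220 genes changed more upward and 1699 more downward in SCNT than in IVF embryos, with a median over all genes of 0.166 on the log2 scale. After quantile normalization, which moved that median to 0.039, the counts were 1784 and 1793. Gstm1, a glutathione transferase gene, changed by 6.17 in SCNT and 0.20 in IVF embryos (difference 5.98, adjusted p = 4e-07), and Impact, an imprinted gene expressed from the paternal copy, by 5.45 and 0.85 (difference 4.59, adjusted p = 7.3e-05). In the other direction, 1700013H16Rik changed by 0.03 and 7.10 (difference −7.06, adjusted p = 5.6e-07), and Rpl39l, a ribosomal protein paralogue, by −3.53 and 2.31 (difference −5.83, adjusted p = 1.3e-05). Transcripts of the 2-cell stage lagged in SCNT embryos in 32 of 38 cases and led in 0, or 37 and 0 adjusted over the list alone (camera adjusted p = 1.23e-21, and adjusted p = 0.00792 with an estimated correlation). The count of genes higher was lower without any single library of the 4 groups, at 1325 to 1710. It was 1368 and 1325 without either IVF 1-cell and 1363 and 1352 without either SCNT 1-cell library.

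At the 2-cell stage, many genes active after IVF were lower in SCNT embryos, some nearly absent, and others stood well above the IVF level. The X-linked gene 1700013H16Rik had 0.0325 ± 0.0167 FPKM in SCNT against 145 ± 13.5 in IVF embryos (log2 −7.14, SE 0.24, adjusted p = 9.2e-09). Rpl39l had 2.29 ± 0.11 against 161 ± 0.928 (log2 −5.63, SE 0.31, adjusted p = 3.4e-07) and Rpl10l, another ribosomal protein paralogue, 0.712 ± 0.305 against 48.2 ± 3.49 (adjusted p = 3.1e-08). Gm13078 fell to 1.69 ± 1.28 from 174 ± 16.9 (log2 −6.11, adjusted p = 7.4e-06), and 1600025M17Rik to 2.1 ± 0.101 from 147 ± 0.402 (adjusted p = 2.8e-05). Gstm1 (chromosome 3, 107815168 to 107820891) stood at 118 ± 17.6 FPKM against 0.203 ± 0.0429 (log2 6.62, SE 0.19, adjusted p = 4.3e-09). Impact (chromosome 18, 13130761 to 13151457) stood at 271 ± 71.8 against 5.56 ± 0.287 (log2 5.35, SE 0.33, adjusted p = 6.7e-07). The necroptosis kinase gene Ripk3 stood at 35.7 ± 1.05 against 0.099 ± 0.0808 (adjusted p = 8.4e-07), and the amino acid transporter gene Slc38a2 at 31.8 ± 2.64 against 0.198 ± 0.061 (adjusted p = 3.4e-07). AF357425 stood at 103 ± 33.8 FPKM and was listed at 0 in IVF embryos, but it is a short transcript whose sampled stretches all occur in another gene, so its value is uncertain. By limma, 4074 genes were higher and 2228 lower in SCNT embryos, 1856 and 1223 of them by at least 2-fold on the scale used. The median over all genes was 0.225, and after quantile normalization, which moved it to 0, the counts were 2791 and 2714, so that the share of calls that were higher went from 64.6% to 50.7%.

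Several lists differed in this comparison by camera, and only that of 2-cell-stage transcripts kept its call with an estimated correlation. Among 38 transcripts of the 2-cell stage 34 fell and 0 rose in SCNT embryos, the same adjusted over the list alone, with a median log2 difference of −1.87 (camera adjusted p = 3.71e-21, and adjusted p = 0.00849 with an estimated correlation). The shared sequence of members, named above, makes these values uncertain. In that list Zscan4d, a zinc finger gene of a family with shared sequence and therefore uncertain values, had 0.563 ± 0.474 against 39 ± 3.48 FPKM (adjusted p = 9.9e-07), and Pramef6, also of a family with shared sequence and uncertain, 0.381 ± 0.415 against 32 ± 1.44. Ribosome biogenesis genes fell in 43 and rose in 1 of 69 cases, or 46 and 1 adjusted over the list alone (adjusted p = 7.55e-15, but adjusted p = 0.427 with an estimated correlation), with Nip7 at 19.1 ± 3.43 against 100 ± 4.93 FPKM. Ribosomal protein genes fell in 49 and rose in 1 of 82, or 54 and 2 adjusted over the list alone (adjusted p = 1.9e-16, but adjusted p = 0.19 with an estimated correlation). Spliceosome genes fell in 34 and rose in 8 of 69, the same adjusted over the list alone (adjusted p = 5.8e-07, but adjusted p = 0.27 with an estimated correlation). Cumulus and granulosa markers rose in 23 and fell in 2 of 58, the same adjusted over the list alone (adjusted p = 0.0234, but adjusted p = 0.394 with an estimated correlation), with S100a11, a gene of uncertain value because of shared sequence, at 22.3 ± 0.715 against 0.777 ± 0.12 FPKM, and their median went from 0.27 to 0.04 after quantile normalization. Markers of other cell types rose and fell in 4 and 0 of 13 cases for immune, 3 and 0 of 6 for oviduct epithelial, 2 and 1 of 5 for endothelial and 0 and 1 of 6 for sperm cells, the same adjusted over each list alone, and camera called none of these (adjusted p = 0.728, 0.297, 0.726 and 0.441). The 1 red blood cell marker tested rose too, but not after quantile normalization, and had no camera test.

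Genes that set or read methylation of histone H3 lysine 9 fell in 8 and rose in 1 of 19 cases, the same adjusted over the list alone (adjusted p = 0.0278, but adjusted p = 0.427 with an estimated correlation). Setdb2 fell to 8.68 ± 0.478 from 22.1 ± 1.92 FPKM and Setdb1 to 3.27 ± 0.576 from 7.74 ± 0.545, both methyltransferase genes. DNA replication and cell cycle genes fell in 20 and rose in 14 of 63, the same adjusted over the list alone (adjusted p = 0.0224, but adjusted p = 0.427 with an estimated correlation), and their median went from −0.19 to 0.01 after quantile normalization. The other lists did not pass camera. DNA methylation genes rose in 4 of 8 cases and fell in 0 (adjusted p = 0.0888), among them Dnmt3l at 25.7 ± 1.4 against 5.66 ± 0.175 FPKM. Imprinted genes rose in 20 and fell in 6 of 41 (adjusted p = 0.158), with Sfmbt2, a Polycomb gene, at 19.6 ± 2.53 against 1.89 ± 0.271. Maternal transcripts rose in 7 and fell in 11 of 65 (adjusted p = 0.329), pluripotency and lineage factors in 4 and 6 of 25 (adjusted p = 0.158), and histone deacetylases in 3 and 3 of 13 (adjusted p = 0.329). Proteasome genes rose in 10 and fell in 8 of 34 (adjusted p = 0.441), and histone genes in 5 and 6 of 27 (adjusted p = 0.504). Adjusted over each list alone these counts were the same, except that 6 maternal transcripts rose.

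Genes activated after IVF made up most of those lower in SCNT than IVF 2-cell embryos. Of the 4086 genes that rose between the stages in IVF embryos, 1636 (40%) were lower in SCNT than IVF 2-cell embryos, where independence would give 676.6, and 635 were higher. Both comparisons use the IVF 2-cell libraries. With 1 of these given to each comparison, 1198 of 3741 and 1267 of 3609 activated genes were lower (odds ratios 10.1 and 10.3). Of the 4074 genes higher in SCNT 2-cell embryos, 1936 (47.5%) were also higher in donor cells than in IVF 1-cell embryos, where independence would give 1727 (odds ratio 1.35, 95% interval 1.25 to 1.45, Fisher's exact p = 2.35e-15). Of the 2228 lower genes, 824 (37%) were, against 944.4 by independence (odds ratio 0.764, 95% interval 0.694 to 0.839, Fisher's exact p = 1.51e-08). Genes are not independent replicates, so these intervals are narrower than the embryos warrant.

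SCNT 2-cell embryos overexpressing Kdm4d had higher levels of many of the genes that were lower in SCNT than IVF 2-cell embryos. Against SCNT 2-cell embryos, 1600025M17Rik rose to 165 ± 75.6 from 2.1 ± 0.101 FPKM (log2 5.66, SE 0.61, adjusted p = 4.2e-05), Gm13078 to 120 ± 18.3 from 1.69 ± 1.28 (adjusted p = 2.5e-05). Mrpl34, a mitochondrial ribosomal protein gene, rose to 130 ± 7.03 from 3.67 ± 0.137 (adjusted p = 8.3e-06). Obox3, of the oocyte-specific homeobox family, rose to 100 ± 14.2 from 4.47 ± 0.834 (adjusted p = 1.8e-06). Gpx2, a glutathione peroxidase gene, fell to 0.44 ± 0.622 from 16.4 ± 5.96 (log2 −3.62, SE 0.28, adjusted p = 7.8e-06). Sfmbt2 fell to 1.09 ± 0.753 from 19.6 ± 2.53 (adjusted p = 2.5e-05). By limma, 2827 genes were higher and 2487 lower. Group weights gave 2267 and 1595, and a fit to these groups only gave 1703 and 1173. Transcripts of the 2-cell stage rose in 32 and fell in 0 of 38 cases, or 33 and 0 adjusted over the list alone (camera adjusted p = 4.72e-13, and adjusted p = 0.0382 with an estimated correlation). Ribosomal protein genes rose in 60 and fell in 0 of 82, or 62 and 0 adjusted over the list alone (adjusted p = 9.44e-15, but adjusted p = 0.179 with an estimated correlation). Ribosome biogenesis genes rose in 42 and fell in 0 of 69, or 45 and 1 adjusted over the list alone (adjusted p = 6.55e-12, but adjusted p = 0.442 with an estimated correlation), and 27 rose and 3 fell after quantile normalization. Cumulus and granulosa markers fell in 16 and rose in 2 of 58, the same adjusted over the list alone (adjusted p = 0.000767, but adjusted p = 0.179 with an estimated correlation). Maternal transcripts rose in 22 and fell in 3 of 65, the same adjusted over the list alone (adjusted p = 0.0169, but adjusted p = 0.673 with an estimated correlation), but 11 rose and 11 fell after quantile normalization.

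Mutant Kdm4d embryos differed from SCNT 2-cell embryos in some genes, and their 2-cell-stage transcripts were not raised. Against SCNT 2-cell embryos, the imprinted gene Phlda2 rose to 45.4 ± 17 from 3.47 ± 0.0641 FPKM (log2 3.33, SE 0.26, adjusted p = 5.2e-05), and Lmo1, a transcription cofactor gene, to 116 ± 10.8 from 10.6 ± 3.82 (adjusted p = 0.00098). Prl3b1, a gene of the prolactin family, stood at 7.45 ± 0.974 and was listed at 0 in SCNT 2-cell embryos. The linker histone gene Hist1h1b fell to 5.17 ± 0.958 from 35.5 ± 10.9 (log2 −2.54, SE 0.37, adjusted p = 0.002), and Pgam2, a glycolysis gene, to 0.48 ± 0.438 from 6.79 ± 0.552 (adjusted p = 0.001). LOC100861570 was listed at 0 against 123 ± 122, a mean that 1 library decided, and its call was lost in several settings. Transcripts of the 2-cell stage fell in 6 of 38 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.0402, but adjusted p = 0.848 with an estimated correlation). Ribosome biogenesis genes fell in 13 and rose in 1 of 69, or 13 and 4 adjusted over the list alone (adjusted p = 0.00209, but adjusted p = 0.999 with an estimated correlation), and 24 fell and 1 rose after quantile normalization. Maternal transcripts rose in 32 and fell in 0 of 65, or 38 and 0 adjusted over the list alone (adjusted p = 4.17e-12, but adjusted p = 0.848 with an estimated correlation), and 17 rose after quantile normalization. By limma, 1515 genes were higher and 863 lower (63.7% of calls higher, against 48.7% after quantile normalization with 1323 and 1394 calls). These counts are fragile. Group weights gave 446 and 118. A fit to these groups only called 0 and 1, with 1635 and 907 at an unadjusted p under 0.05, where chance would give 673 in all. Without SCNT 2-cell replicate 1 they were 427 and 171, without its replicate 2 820 and 465, and without mutant replicate 1 or 2 the genes lower were 436 or 2089.

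Kdm4d and mutant Kdm4d embryos, compared directly, differed in many of the genes that were lower in SCNT than IVF 2-cell embryos. Measured Kdm4d levels also differed between them, as given above. Median log2(FPKM + 1) of the maternal list was 5.06 and 4.74 in Kdm4d libraries. It was 5.57 and 5.1 in mutant Kdm4d and 4.72 and 4.66 in SCNT 2-cell libraries. Neither the amount of Kdm4d nor collection time was tested as a source of the differences between these groups. Gm13078 (chromosome 4, 143309358 to 143319061) stood at 120 ± 18.3 FPKM against 2.42 ± 3.21 (log2 5.56, SE 0.55, adjusted p = 3.5e-05). Obox3 stood at 100 ± 14.2 against 5.14 ± 2.53 (log2 4.10, SE 0.24, adjusted p = 2.4e-06), and B020004J07Rik at 46 ± 1.78 against 2.01 ± 0.968 (adjusted p = 2.4e-06). Dub1a, a deubiquitinase gene of a multi-copy family and of uncertain value, stood at 359 ± 33.5 against 26.8 ± 22 (adjusted p = 5.4e-05). Rnase4 was lower with Kdm4d, at 0.0137 ± 0.0194 against 10.9 ± 1.07 (log2 −3.55, SE 0.31, adjusted p = 1.7e-05). So were Tmem37 at 6.3 ± 3.32 against 56.9 ± 9.27 (adjusted p = 1.6e-05) and Ambp at 0.0176 ± 0.0248 against 7.07 ± 1.03 (adjusted p = 2.4e-06). By limma, 2874 genes were higher and 3022 lower with Kdm4d. With group weights 1447 and 795 were called, the genes named here among them. A fit to these 4 libraries only called 0 genes in either direction (lowest adjusted p = 0.062, with 2063 and 1828 at an unadjusted p under 0.05, where chance would give 673 in all).

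Of the 6 lists low in SCNT against IVF 2-cell embryos by camera, 5 were high in that direct comparison, and the exception was the list of histone H3 lysine 9 methyltransferases and readers (8 rose and 2 fell of 19, the same adjusted over the list alone, adjusted p = 0.0509, and adjusted p = 0.431 with an estimated correlation). Transcripts of the 2-cell stage rose with Kdm4d in 34 and fell in 0 of 38 cases, the same adjusted over the list alone (camera adjusted p = 1.32e-16, and adjusted p = 0.0187 with an estimated correlation). Ribosome biogenesis genes rose in 64 and fell in 0 of 69, the same adjusted over the list alone (adjusted p = 1.12e-19, but adjusted p = 0.303 with an estimated correlation), with Imp3 at 62.2 ± 12 against 9.47 ± 2.47 FPKM. Ribosomal protein genes rose in 59 and fell in 1 of 82, or 64 and 1 adjusted over the list alone (adjusted p = 5.8e-15, but adjusted p = 0.24 with an estimated correlation). Spliceosome genes rose in 36 and fell in 3 of 69, or 37 and 4 adjusted over the list alone (adjusted p = 1e-05, but adjusted p = 0.3 with an estimated correlation). Replication and cell cycle genes rose in 29 and fell in 5 of 63, or 32 and 6 adjusted over the list alone (adjusted p = 0.000325, but adjusted p = 0.303 with an estimated correlation). Proteasome genes rose in 17 and fell in 4 of 34, or 20 and 4 adjusted over the list alone (adjusted p = 0.00141, but adjusted p = 0.454 with an estimated correlation), and 11 rose and 5 fell after quantile normalization. Cumulus and granulosa markers fell in 18 and rose in 3 of 58, the same adjusted over the list alone, with Anxa2 at 3.78 ± 0.057 against 21.1 ± 1.69 FPKM (adjusted p = 0.00603, but adjusted p = 0.3 with an estimated correlation). Oviduct epithelial markers fell in 3 and rose in 1 of 6 cases, and immune markers in 1 and 1 of 13. Endothelial markers fell in 1 and rose in 1 of 5, and sperm markers in 0 and 2 of 6. Camera called none of these 4 lists. The 1 red blood cell marker tested fell, with no camera test. Maternal transcripts fell in 19 and rose in 4 of 65, or 17 and 4 adjusted over the list alone (adjusted p = 0.00883, but adjusted p = 0.558 with an estimated correlation), and 4 rose and 32 fell after quantile normalization.

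Many of the genes lower in SCNT than IVF 2-cell embryos were higher with Kdm4d. Of the 2228 genes lower in SCNT than IVF 2-cell embryos, 1650 (74.1%) were higher with Kdm4d than with mutant Kdm4d, where independence would give 475.9 (odds ratio 23.3, 95% interval 20.8 to 26.1), and 23 were lower. Of the 4074 genes higher in SCNT embryos, 1920 (47.1%) were lower with Kdm4d than with mutant Kdm4d, against 915 (odds ratio 6.7, 95% interval 6.13 to 7.32), and 124 were higher. These shares depend on the spread assumed. With group weights in the Kdm4d comparison they were 1088 (48.8%) of the 2228 (odds ratio 28.9, 95% interval 25.2 to 33.1) and 639 (15.7%) of the 4074 (odds ratio 11, 95% interval 9.18 to 13.2). A fit to the 4 Kdm4d libraries only, with 0 calls by limma and 2063 and 1828 at an unadjusted p under 0.05, gave no overlap. These comparisons share no library, and Spearman's rho of their log2 differences across 13455 genes was −0.63. The 2228 genes had a median log2 difference of −1.06 between SCNT and IVF 2-cell embryos, 0.99 between Kdm4d and mutant, 1.03 between Kdm4d and SCNT, 0.02 between mutant and SCNT and −0.09 between Kdm4d and IVF 2-cell embryos. For the 4074 genes these medians were 0.94, −0.51, −0.57, −0.11 and 0.40, in the same order. Against SCNT 2-cell embryos, which both sides then share, 1737 (78%) of the 2228 were higher and 2065 (50.7%) of the 4074 lower with Kdm4d. With group weights these were 1547 (69.4%) and 1426 (35%). With 1 SCNT 2-cell library given to each comparison, 1257 of 1683 and 1223 of 1860 genes lower in SCNT embryos were higher with Kdm4d, and 1216 of 3179 and 1287 of 3029 higher ones lower. Across genes, rho of that difference with the SCNT effect was −0.77 (simulated −0.47, covariance −0.585 against −0.028). In these simulations SCNT and IVF embryos did not differ either, unlike in the data. The simulated rho is thus not the chance value for these data, for either construct. For mutant Kdm4d, rho was −0.13 (simulated −0.48, covariance −0.07 against −0.028), with 319 (14.3%) of the 2228 genes higher against 250.9 by independence, and 151 lower. On split libraries the genes higher were 91 of 1683 (odds ratio 1.96) and 112 of 1860 (odds ratio 0.985), so that this overlap rests on which library is used. Of the 4074 genes, 420 (10.3%) were lower with mutant Kdm4d against 261.3 by independence (odds ratio 2.32), and 297 were higher. On split libraries the odds ratios for the genes lower were 3.14 and 2.04. With group weights 116 of the 2228 were higher and 24 lower with mutant Kdm4d (odds ratio 1.81 for the 116). Of the 4074, 61 were lower and 64 higher (odds ratio 2.49 for the 61).

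**Figure D3:**
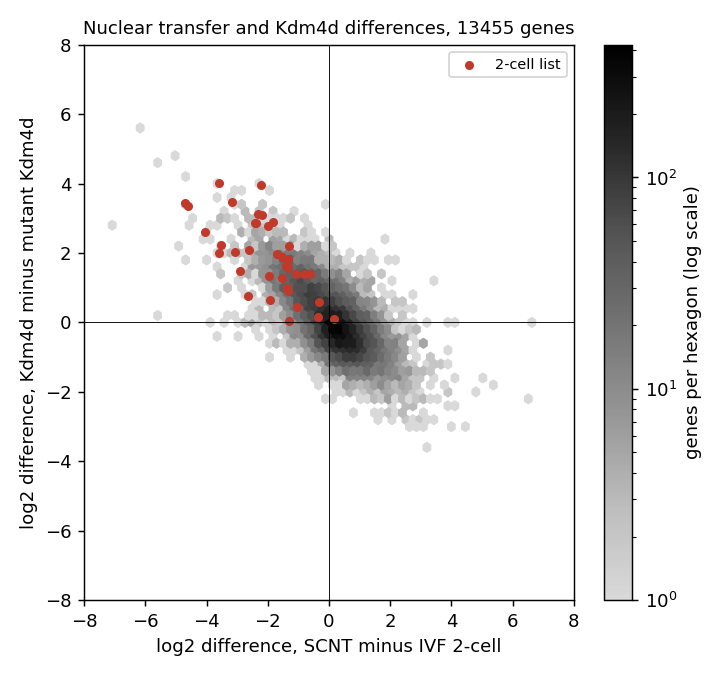
Log2 difference between SCNT and IVF 2-cell embryos (horizontal) and between Kdm4d and mutant Kdm4d SCNT embryos (vertical) for 13455 genes (shaded hexagons, darker with more genes) and the 38 genes of the 2-cell-stage list (red points). The genes lie along a falling diagonal (rho −0.63 across genes).

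Kdm4d SCNT 2-cell embryos still differed from IVF 2-cell embryos. Besides Kdm4d itself (log2 11.47, SE 0.52, adjusted p = 2.2e-07), Gstm1 stayed high at 23.7 ± 5.65 against 0.203 ± 0.0429 FPKM (log2 4.34, SE 0.19, adjusted p = 2e-07), as did the imprinted gene Impact at 68.5 ± 38.4 against 5.56 ± 0.287 (adjusted p = 9.8e-05). Sf3b5, the gene of a splicing factor subunit, stood at 302 ± 5.52 against 29.2 ± 0.44 (adjusted p = 0.00025). Low in Kdm4d embryos were 1700013H16Rik at 6.53 ± 3.1 against 145 ± 13.5 (log2 −4.33, SE 0.24, adjusted p = 1.2e-06), Rpl39l at 9.64 ± 5.32 against 161 ± 0.928 (adjusted p = 1.1e-05) and Sycp1, a gene of the synaptonemal complex, at 2.75 ± 1.47 against 57.8 ± 4.24 (adjusted p = 3.5e-06). The Y-linked gene Eif2s3y was listed at 0 against 13.4 ± 2.47 FPKM, a difference fixed by the design, since the SCNT nuclei came from female cells. Transcripts of the 2-cell stage fell in 12 and rose in 1 of 38 cases, the same adjusted over the list alone (camera adjusted p = 1.12e-09, but adjusted p = 0.0818 with an estimated correlation). Proteasome genes rose in 15 and fell in 0 of 34, or 21 and 0 adjusted over the list alone (adjusted p = 0.000115, but adjusted p = 0.834 with an estimated correlation), and 9 rose after quantile normalization. Oxidative phosphorylation genes rose in 29 and fell in 2 of 82, or 35 and 2 adjusted over the list alone (adjusted p = 0.00229, but adjusted p = 0.834 with an estimated correlation), and 19 rose and 3 fell after quantile normalization.

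By limma, 2233 genes were higher and 498 lower in Kdm4d than in IVF 2-cell embryos, with a median over all genes of 0.183. After quantile normalization, which moved that median to −0.013, 918 were higher and 1039 lower, so that the share higher went from 81.8% to 46.9%. Of the 498, 327 were also lower in SCNT 2-cell embryos, and of the 2233, 1242 were also higher there. Both comparisons use the IVF 2-cell libraries. With 1 of these given to each comparison, 148 of 197 and 161 of 229 lower genes were also lower in SCNT embryos, and 54.8% of 867 and 48.8% of 1182 higher ones also higher. Group weights gave 1471 and 293, and a fit to these groups only 101 and 36, with 2782 and 684 at an unadjusted p under 0.05. Without IVF 2-cell replicate 1 the counts were 1183 and 226, and without its replicate 2 they were 886 and 203.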

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

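Of the tests in this part, those of collection time, of genes with no shared stretch, of scaling and of split libraries were chosen after the result was seen.

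The change between the 1-cell and 2-cell stages differed between SCNT and IVF embryos by limma's interaction test, with 2220 genes higher and 1699 lower. The differences of log2 changes were 6.66 for AF357425, 5.98 for Gstm1, 5.06 for Ripk3, 4.59 for Impact, 4.30 for Tmem37 and 3.95 for Gsta4. Downward they were −7.06 for 1700013H16Rik, −6 for Gm13078, −5.83 for Rpl39l, −5.37 for 1600025M17Rik, −5.01 for Zscan4d and −5.00 for Akr1c18. Some genes moved in opposite directions: Rpl39l changed by −3.53 in SCNT and 2.31 in IVF embryos, Zscan4d by −1.24 and 3.77, and Akr1c18 by −3.01 and 1.99. Akr1c18 already differed at the 1-cell stage, at 31.3 FPKM in SCNT against 0.0569 in IVF embryos. Gsta4 changed by 0.04 in SCNT and −3.91 in IVF embryos. Lists that lagged in SCNT embryos by camera were 2-cell-stage transcripts (32 lagged and 0 led of 38 genes, adjusted p = 1.23e-21), ribosome biogenesis (30 and 1 of 69, adjusted p = 5.54e-12), ribosomal proteins (40 and 1 of 82, adjusted p = 1.19e-14) and spliceosome (28 and 4 of 69, adjusted p = 9.35e-06). Replication and cell cycle genes also passed (20 and 10 of 63, adjusted p = 0.0436) but were nearly balanced after quantile normalization (13 and 10), with the median going from −0.21 to −0.11. With an estimated correlation the first kept its call (adjusted p = 0.00792) and the others did not (adjusted p = 0.511, 0.245, 0.395 and 0.511).

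A pattern at the 2-cell stage, 1636 of 4086 activated genes lower in SCNT than IVF 2-cell embryos, was set against technical explanations. Its overlap with the interaction calls was not counted. Reads shared between gene copies as the whole cause are argued against: 37.6% of the 1312 activated genes with no shared stretch were lower (493 genes). For scaling of FPKM, 45.5% of activated genes were lower after quantile normalization, but the test cannot decide. That step moved the median difference over all genes from 0.225 to 0, which by itself makes more genes lower. Scaling to equal sums of FPKM was not run. Because SCNT 2-cell libraries had lower sums, it would move their values up against IVF 2-cell embryos. Among the lower genes, 36.7% (interval 34.2% to 39.2%) shared over 5% of their stretches, against 32.5% of all activated genes, which lies between the bounds set for this test, so a part played by shared reads cannot be told apart. Collection of SCNT embryos at an earlier point cannot be told apart either: maternal transcripts had a median difference to IVF 2-cell embryos of −0.07 relative to all genes (bootstrap interval −0.27 to 0.03) with members going both ways, but of the 5000 genes that fell in IVF embryos 1826 were higher in SCNT 2-cell embryos and 292 lower, with a median of 0.14 relative to all genes, and with 1 of the shared IVF 2-cell libraries given to each comparison 1149 of 4452 and 1123 of 4494 were higher (odds ratios 1.41 and 1.42). The strain of the oocytes and the sex of the embryos, which differ with the kind of embryo, stay open and untested. So does the difference in nuclear transfer itself. By the strain labels the genomes came from the same cross of strains in both kinds of embryo. They differ if the BDF1 source named in the protocols is right, so the strain of the genomes stays open too.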

How the results depend on the processing

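Group weights were chosen after the spread between groups was seen, and the other alternatives of this part before.

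The counts of IVF stage changes, SCNT stage changes, SCNT against IVF 2-cell embryos and donor against IVF 1-cell embryos stayed within 1.5 times their values under every alternative run, including each left-out library. The share of genes lower in SCNT 2-cell embryos that were higher with Kdm4d than mutant Kdm4d, the donor-enriched share of genes higher there and the share of activated genes lower there kept their direction and side of the threshold where an alternative could give them. Other overlaps were not counted under these alternatives. Named genes kept direction and call in most cases: 124 with a pseudocount of 0.1 (1 stronger, 2 weaker), 125 with no filter (2 weaker), 125 with quantile normalization (1 weaker, 1 reversed), 102 in a fit to only the groups compared (1 stronger, 24 weaker), 122 with group weights (1 stronger, 4 weaker), 127 with a replicate block, and 506 in fits without a library (22 weaker). The reversed value is Kdm4d between SCNT and IVF 1-cell embryos, 0.08 and −0.07 after quantile normalization, below 1 FPKM in all libraries and far from the threshold.

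With an estimated correlation between genes in camera fewer lists passed, and the cause was not tested. The estimates, against the preset 0.01, were 0.486 for ribosome biogenesis, 0.0597 for 2-cell-stage transcripts and 0.0273 for cumulus and granulosa markers. A lost call thus does not by itself show that members of a list vary strongly together. After IVF 1 rose and 0 fell (from 5 and 2), and between the SCNT stages 0 and 0 (from 4 and 2). In the interaction 1 was lower (from 5). SCNT against IVF gave 0 and 0 (from 1 and 1) at the 1-cell and 0 and 1 (from 1 and 6) at the 2-cell stage. Kdm4d against SCNT gave 1 and 0 (from 8 and 1), mutant against SCNT 0 and 0 (from 1 and 2), Kdm4d against mutant 1 and 0 (from 6 and 2), Kdm4d against IVF 0 and 0 (from 2 and 1), and donor cells 1 and 0 (from 4 and 4).

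A fit to only the groups compared no longer borrows their spread from the others. The interaction then called 3791 genes higher and 2618 lower (from 2220 and 1699), and SCNT against IVF 1-cell 1609 and 1166 (from 180 and 131). Kdm4d against SCNT called 1703 and 1173 (from 2827 and 2487), mutant against SCNT 0 and 1 (from 1515 and 863), Kdm4d against mutant 0 and 0 (from 2874 and 3022), and Kdm4d against IVF 101 and 36 (from 2233 and 498). With 0 calls, this alternative could give no overlap of the Kdm4d and mutant comparison with the genes lower in SCNT embryos. Group weights moved the same counts in the same directions: 3937 and 2652 for the interaction, 2548 and 1530 at the 1-cell stage, 1595 genes lower for Kdm4d against SCNT, 446 and 118 for mutant against SCNT, 1447 and 795 for Kdm4d against mutant and 1471 and 293 for Kdm4d against IVF. Both alternatives change the variance used, and the fit to only the groups compared also has fewer residual degrees of freedom, and these parts were not separated. By these weights, a different measure from the robust SD, the variance relative to IVF 1-cell embryos was 9.15 times in Kdm4d and 11.7 times in mutant Kdm4d embryos, and the joint fit uses 1 variance for all. Of the calls of Kdm4d against mutant, all 1447 and 795 with group weights were among the 2874 and 3022.

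Quantile normalization gave 78 and 66 genes at the 1-cell stage, 1394 lower for mutant against SCNT, and 918 and 1039 for Kdm4d against IVF. It changed the lists passing camera to 2 rising in the interaction (from 0), 3 rising between SCNT and IVF 2-cell embryos (from 1), 5 rising and 2 falling for Kdm4d against SCNT (from 8 and 1), and 2 rising for mutant against SCNT (from 1); the cause was not tested. A pseudocount of 0.1 gave 601 genes higher at the 1-cell stage with 2 rising lists (from 1), and 1 falling list for mutant against SCNT (from 2); the cause was not tested. With no filter, rho of the SCNT and Kdm4d differences across genes was −0.57 (from −0.631), where more genes near 0 enter by construction. A block for replicate number gave 87 genes lower at the 1-cell stage (from 131). Replicate numbers did not pair the libraries: over 21 pairs of groups, correlations of the replicate differences ran from −0.15 to 0.19.

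Leaving out a library leaves a group of 1, assumed to vary like the others, and fewer samples by construction. At the 1-cell stage 36 to 47 genes were higher and 7 to 11 lower, whichever library was left out. The interaction gave 1325 to 1710 higher, lowest without IVF 1-cell replicate 2. Mutant against SCNT gave 427 to 2140 higher and 171 to 2089 lower, both lowest without SCNT 2-cell replicate 1 and highest without mutant replicate 2. Kdm4d against IVF gave 886 to 2340 higher and 203 to 564 lower, both lowest without IVF 2-cell replicate 2. The correlation across genes of the SCNT and Kdm4d differences ran from −0.668 without mutant replicate 1 to −0.545 without mutant replicate 2, and was −0.58 without Kdm4d replicate 1. Calls of Elovl5, Fam84a, Kcnn2 and Zfp352 at the 1-cell stage and of Tgoln2 and LOC100861570 in mutant embryos were lost without single libraries. All 4 comparisons with a Kdm4d or mutant group had more calls in the joint fit than with group weights or in a fit to only the groups compared, so the joint counts may be too high.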

Other observations

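Genes named here from the Y chromosome, Xist, Slc38a4, Gab1, H19 and Igf2 were chosen after their values were seen, and so were the tests by chromosome and the check of how selection acts on the donor RNA test, while the tests on donor RNA and on neighbouring genes were set before their results were seen.

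Y-linked transcripts were found in IVF 2-cell embryos and lay near 0 in all other groups. Cumulus cells come from females, so SCNT embryos hold no Y chromosome and this difference from IVF 2-cell embryos is fixed by the design. The sex of the embryos thus differed with their kind. Its part in the values of Xist and of X-linked genes below was not tested. Eif2s3y had 13.4 ± 2.47 FPKM (SD, n = 2) and Uty 5.53 ± 1.75 in IVF 2-cell embryos, and both were listed at 0 in SCNT 2-cell and mutant Kdm4d embryos. Xist, the noncoding RNA of X inactivation (chromosome X, 100655712 to 100678572), had 4.78 ± 0.275 FPKM in SCNT 2-cell embryos against 0.193 ± 0.0397 in IVF 2-cell embryos (log2 2.28, SE 0.21, limma adjusted p = 7.8e-06). It stood at 0.458 ± 0.205 with Kdm4d and 2.14 ± 0.846 with mutant Kdm4d (log2 −1.09, SE 0.21, adjusted p = 0.0015). A fit to these 4 libraries only called 0 genes, so this call was lost there. Against SCNT 2-cell embryos Xist was lower with Kdm4d (log2 −1.99, limma adjusted p = 3.5e-05) and with mutant Kdm4d (log2 −0.91, adjusted p = 0.013). In donor cells it stood at 8.86 ± 1.82 FPKM. X-linked genes as a set, 492 of those tested, had a median log2 difference of 0.02 between SCNT and IVF 2-cell embryos, where all genes had 0.23, and camera did not call them (adjusted p = 0.106 over 20 chromosomes). Between Kdm4d and IVF 2-cell embryos their median was 0.07 against 0.18 (adjusted p = 0.00659, but adjusted p = 0.0887 with an estimated correlation).

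Some imprinted genes high in SCNT 2-cell embryos were lower with Kdm4d and others were not. Of the 41 imprinted genes tested, 8 rose and 14 fell with Kdm4d against SCNT 2-cell embryos (camera adjusted p = 0.491). Against mutant Kdm4d 6 rose and 13 fell (adjusted p = 0.286). Slc38a4 had 3.41 ± 0.587 FPKM in SCNT, 0.202 ± 0.277 in IVF, 1.48 ± 0.475 in Kdm4d and 3.34 ± 0.12 in mutant Kdm4d embryos at the 2-cell stage, and Sfmbt2 19.6 ± 2.53, 1.89 ± 0.271, 1.09 ± 0.753 and 9.37 ± 5.06. Gab1 had 3.02 ± 0.064, 0.205 ± 0.163, 3.22 ± 0.156 and 3.21 ± 0.555. The imprinted genes Phlda2, H19 and Igf2 were not called higher in SCNT than IVF 2-cell embryos. Phlda2 (chromosome 7, 150687453 to 150688429) had 18.3 ± 0.383 FPKM in IVF and 3.47 ± 0.0641 in SCNT 2-cell embryos (log2 −2.11, SE 0.26, adjusted p = 6e-05), 53.5 ± 14 with Kdm4d and 45.4 ± 17 with mutant Kdm4d, and the 2 Kdm4d groups did not differ by limma (log2 0.26, SE 0.26, adjusted p = 0.44), while Kdm4d embryos lay above IVF embryos (log2 1.47, SE 0.26, adjusted p = 0.0026). On the same chromosome, H19 was listed at 0 and Igf2 at 0.0869 ± 0.0463 FPKM in IVF 2-cell embryos. From SCNT 2-cell embryos H19 rose from 0.00938 ± 0.0133 FPKM to 2.21 ± 0.475 with Kdm4d (adjusted p = 6.3e-05) and 2.46 ± 1.16 with mutant Kdm4d (adjusted p = 0.00075), and Igf2 from 0.125 ± 0.135 to 1.32 ± 0.434 (adjusted p = 0.00026) and 1.63 ± 0.092 (adjusted p = 0.001). A fit to only the mutant Kdm4d and SCNT 2-cell groups called 0 genes higher, so the mutant calls were lost there.

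The 147 donor-enriched genes higher in SCNT than IVF 1-cell embryos raised the hypothesis that RNA came in with the donor cell. The most abundant donor-only genes set the scale: 69 genes with at least 100 FPKM in donor cells and under 1 in IVF embryos had a median excess in SCNT embryos of 0.379% of the donor level (interval 0.249% to 0.422%), and 66 of 69 lay above IVF, with Spp1 at 0.171%, Akr1c18 at 0.91% and Cyp11a1 at 0.149%. For 57 of the called genes present in IVF embryos the median excess was 9.89% of the donor level (6.48% to 16.3%), above the bound of 3.79% set as 10 times the reference, but for 61.4% of them the smallest rise that was called would alone exceed that bound, so the selection of called genes fixes the outcome and carried RNA cannot be told apart. For 90 called genes under 1 FPKM in IVF embryos the median was 7.86%, but its interval of 2.68% to 10.9% spans the bound. For 46.7% of them the smallest called rise would alone exceed the bound, so the selection acts on this median too. The 90 genes and the reference are not separate sets, since Spp1 and Akr1c18 are in both. Carried RNA may explain part of the 90 genes and cannot be told apart from transcription after transfer. Gt(ROSA)26Sor reached 34.6% and 2610019E17Rik 37.7% of the donor level, and the strain of the oocytes stays open and untested for all of them.

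Activated genes lower in SCNT 2-cell embryos were tested for lying next to each other in the genome. Of 4076 placed activated genes 1630 were lower, and 684 adjacent pairs were both lower, where 10000 permutations within 10 bins of IVF 2-cell expression gave a median of 655 and a 95% range of 625 to 685 (one-sided p = 0.0334, ratio 1.04). The count lies within the range that chance allows given the expression of the genes, as set before the test. Without pairs of one gene family or with shared stretches 613 pairs remained (permuted median 615, range 585 to 645, permutation p = 0.554), so tandem copies of gene families as a source of the small excess cannot be told apart from chance.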
